A study of Homo sapiens with 12 samples.

How the data were processed

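Total RNA of IgG-positive and IgG-negative PL45 cells was measured by sequencing in 12 libraries, 3 for each of 4 groups (ascites A1 or A14, IgG-positive or IgG-negative). Per the labels, cells were blocked, incubated with ascitic IgG, stained with a labelled anti-human IgG antibody and sorted. The libraries were stranded total RNA libraries depleted of ribosomal RNA. The submitters' processing notes name bcl2fastq 2.20.0, fastp 0.23.4, RSEM 1.3.3 and DESeq2, with the hg38 genome. The version of DESeq2, the aligner and the gene annotation are not given in the sources used here.

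The deposited table holds expected counts, which per the file headers and the processing notes the authors estimated for each gene with RSEM and did not normalize for depth, and 5.84% of its values are not whole numbers. It has 26489 features named by gene symbol, 28 of them in the form of a date, and 6631 had no count in any library. Library totals were 17.2 M to 39.8 M counts (M, megacounts). Reads had no molecular identifiers, so that intervals and floors cover counting error only; the floor used for a gene with a count of 0 was 3 counts. Gene positions came from RefSeq genes by symbol. Transcript lengths and GC content came from GENCODE release 29 by symbol, which matched 92.7% of distinct symbols. Length was known for 97.0% of tested genes.

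Counts were rounded and filtered with filterByExpr by group, which left 14337 features, and scaled by TMM. Tests used edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test on a model of the 4 groups and no covariate, and Benjamini-Hochberg adjusted p values with a threshold of 0.05. The biological coefficient of variation was 0.151, with 8 residual degrees of freedom. The comparisons were IgG-positive against IgG-negative cells with A1, with A14 and as the mean of both, the difference of the sort effect between A14 and A1, and A14 against A1 over both fractions. The groups, comparisons, gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined.

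The rule named, for each sort comparison, the 10 called genes with the largest rise and the 10 with the largest fall. They had to have a mean log2 CPM (counts scaled to a common library size) of at least 1 and no overlap between the fractions within an ascites, and small RNA and non-coding symbols of listed prefixes were left out. Y RNAs were not among those prefixes, so RNY3 and RNY1 stayed eligible. Where fewer than 5 genes qualified, the 5 with the smallest unadjusted p in each direction were given as values that did not pass, and 3 in each direction for the difference between ascites and for A14 against A1. Up to 4 members of each list were eligible, by smallest p.

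A total of 36 gene lists covered cell states, surface molecules and glycosylation, signs of RNA quality and other cell types. The 32 lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with others, were alternatives.

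The labels give 3 batches. In both ascites the IgG-negative libraries lay in batches 1, 1 and 2 and the IgG-positive ones in 2, 3 and 3, so that the sort nearly followed the batch. The labels do not say whether same-numbered libraries were paired, nor whether replicates were separate cultures and stainings or repeated sorts. The column taken as A1 IgG-negative replicate 2 carries an extra tag, ERS, that the labels do not explain, and was matched by the rest of its name. Within A1 the deviations of same-numbered libraries from their groups correlated across genes at 0.426, 0.200 and 0.248. There 6 of 6 libraries correlated best with the library of their own number, so the A1 counts with a replicate block are given beside those without. In fits with libraries of both ascites that block is 1 term shared by A1 and A14. No pair of replicates was alike enough to be the same library.

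Other settings of that first set were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter, a filter at 1 CPM, the replicate block, batch as a term, leaving out each library, leaving out mitochondrial genes and the 20 features with the most counts, a 2-fold minimum, fits of the 6 libraries of an ascites and of the 4 libraries of batch 2. Settings chosen after seeing the data were a correction of each library for its trend with transcript length and GC content (splines with 5 degrees of freedom each), that correction with the replicate block, the 6 libraries of an ascites with the block, leaving out A1 IgG-positive replicate 1 and A14 IgG-positive replicate 2, and leaving out both A1 replicate 1 libraries. The fits were tested on simulated data with 200 changed genes of 14337. At a log2 change of 1 they recovered 73.5% with A1, 77% with A14 and 79.5% for the mean, and at 0.5 they recovered 0%, 2% and 41.5%. The simulated libraries had no trend with length, no batch and no link between same-numbered libraries. These shares may therefore overstate recovery in the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.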

Results

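PL45, an established cell line from a pancreatic ductal adenocarcinoma, was stained with IgG from 1 of 2 ascites fluids, A1 or A14. The cells were sorted into IgG-positive and IgG-negative fractions, and total RNA was sequenced after depletion of ribosomal RNA. Each combination of ascites and fraction had 3 libraries, 12 in all, and the labels do not say whether these were separate cultures and stainings or repeated sorts. The total count per library ranged from 17.2 M to 39.8 M counts (M, megacounts). Group means were 35.4 ± 6.96 M for A1 IgG-negative, 19.5 ± 3.98 M for A1 IgG-positive, 34.1 ± 4.16 M for A14 IgG-negative and 25.2 ± 4.04 M for A14 IgG-positive cells (SD, n = 3 each). The IgG-positive libraries were smaller by a mean difference of -12.4 M counts (two-sided exact permutation test, p = 0.00433, 6 libraries against 6). Per the series text, the sort was made to look for transcripts that go with the binding of ascitic IgG to part of the cells.

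Across both ascites, IgG-positive cells carried more mRNA for surface mucins and for regulators of epithelial identity. MUC16, the membrane mucin that carries the CA125 antigen (hg38 chromosome 19, 8848844 to 9065751), rose 6.69-fold (log2 fold change 2.74 ± 0.47 SE, 6 libraries against 6; edgeR adjusted p = 0.00673). MUC1, another membrane mucin (chromosome 1, 155185824 to 155192915), rose 4.94-fold (2.30 ± 0.37; edgeR adjusted p = 0.00525). CEACAM6, a cell adhesion glycoprotein of carcinomas (chromosome 19, 41755530 to 41772211), rose 4.60-fold (SE 0.43 on the log2 scale; edgeR adjusted p = 0.0110). GRHL2, a transcription factor that maintains epithelial junctions (chromosome 8, 101492439 to 101681200), rose 3.68-fold (1.88 ± 0.21; edgeR adjusted p = 0.00208). The largest fall among the named genes was that of RNY3, a small cytoplasmic Y RNA bound by the Ro60 protein (chromosome 7, 148983755 to 148983856), whose log2 fold change was -1.83 ± 0.28 (edgeR adjusted p = 0.00492). All 5 calls held in each of the 12 fits that left out 1 library. With batch as a term none of the 5 passed: the edgeR adjusted p was 0.572 for MUC16, 0.513 for MUC1, 0.661 for CEACAM6, 0.503 for GRHL2 and 0.572 for RNY3, with log2 fold changes of 2.99, 2.68, 1.51, 1.63 and -1.50.

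The levels behind these changes were low for the mucins. MUC16 stood at 2.21 ± 1.38 CPM (counts scaled to a common library size) in A1 IgG-negative and 17.3 ± 11.6 in A1 IgG-positive cells, and at 1.66 ± 0.672 and 9.29 ± 7.24 with A14 (SD, n = 3 per group). GRHL2 stood at 5.12 ± 1.23 and 22.6 ± 3.84 with A1 and at 6.46 ± 1.58 and 19.8 ± 7.71 with A14. The other genes named by the rule that rose were the epithelial transcription factor EHF (log2 fold change 1.89), the adhesion receptor ADGRF1 (1.86), the tensin TNS4 (1.79), the tetraspanin TSPAN1 (1.79), the serpin SERPINB5 (1.78) and the O-glycosylation enzyme GALNT5 (1.75). Those that fell were ND6, a complex I subunit encoded in the mitochondrial genome (-0.98), the Y RNA RNY1 (-0.87), the small GTPase RERG (-0.84), the keratin KRT10 (-0.82), the RNA-binding protein RBM24 (-0.74), HNRNPA0, an RNA-binding protein of the nucleus (-0.72), GAR1, a protein of H/ACA ribonucleoproteins (-0.69), the catenin CTNNA2 (-0.67) and the adenosine receptor ADORA1 (-0.62). The rule admitted only genes without overlap between the fractions. That all 3 IgG-positive libraries lay on the same side of all 3 IgG-negative libraries for these 20 genes is therefore no separate result. Of all tested genes, 9.06% had no such overlap in both ascites.

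**Figure D1:**
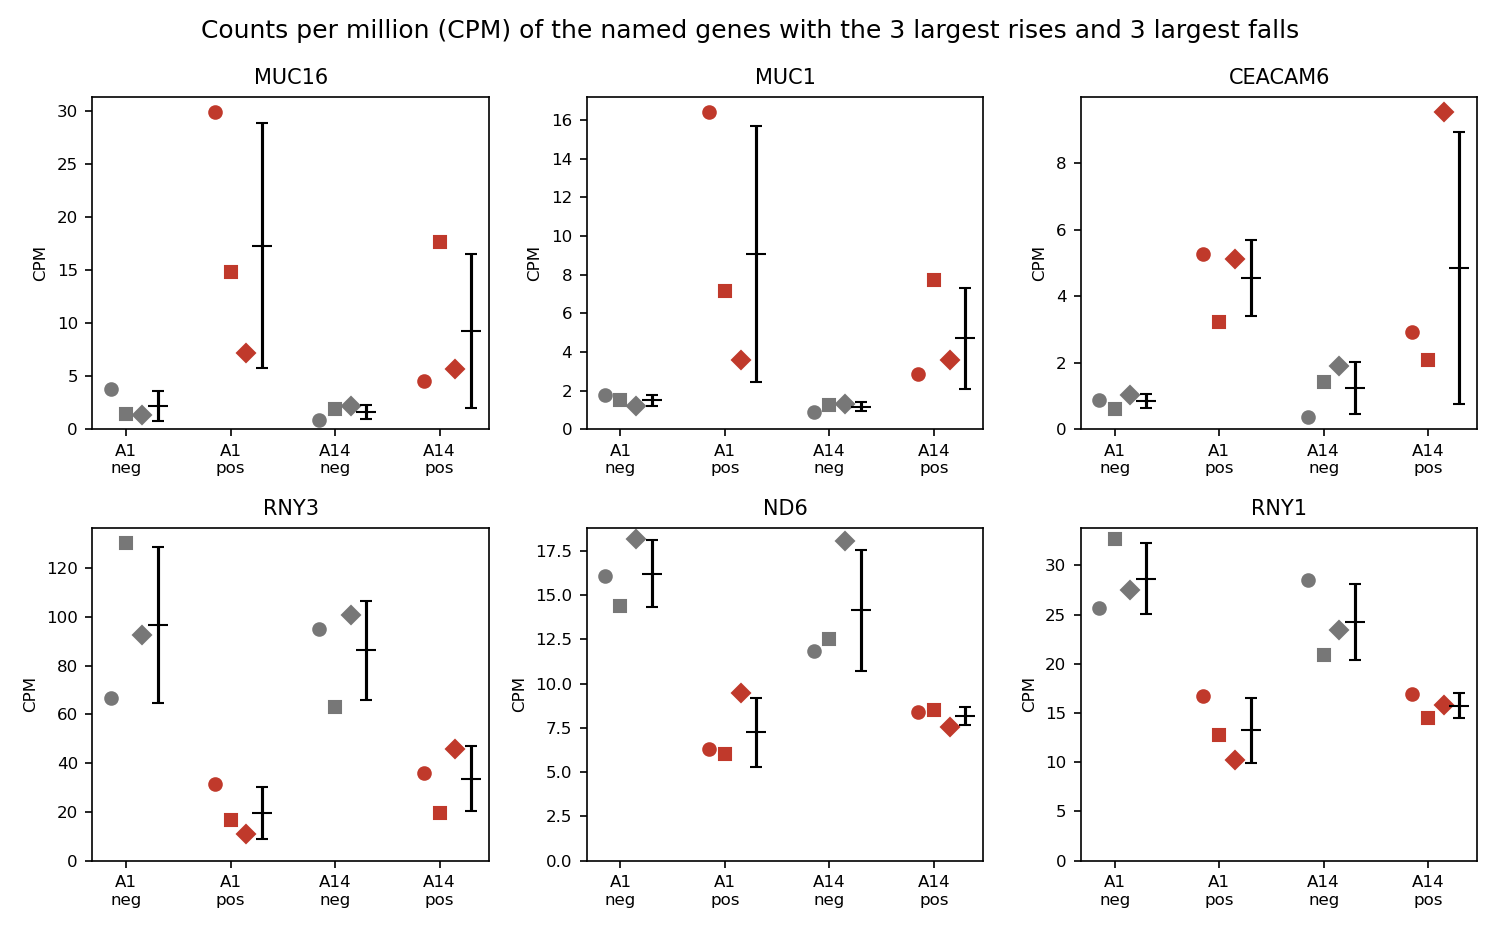
CPM, on linear axes from 0, of MUC16, MUC1, CEACAM6, RNY3, ND6 and RNY1 in each of the 12 libraries, by ascites and sort fraction. Grey points are IgG-negative and red points IgG-positive libraries. Circles, squares and diamonds are replicates 1, 2 and 3, and the black bar is the mean ± SD of 3 libraries. In both ascites the red points lie above the grey ones for MUC16, MUC1 and CEACAM6 and below them for RNY3, ND6 and RNY1. The rule for named genes admitted only genes without overlap between the fractions.

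Epithelial identity genes moved together. Of 22 tested members, 14 rose and 0 fell over all genes tested, and 16 rose when adjusted over the list alone, with a median log2 fold change of 0.75. They included GRHL2, the splicing regulator ESRP1 (1.32), the transcription factor OVOL1 (1.54) and the tight junction protein CLDN7 (1.56). The list passed with limma's camera at the preset correlation (adjusted p = 4e-10), and gave adjusted p = 0.316 with an estimated correlation. With the 2 ascites taken apart in batch 2, the only batch with both fractions, the difference of the list's mean log2 CPM was 0.663 with A1 and 0.686 with A14, against 0.737 in all batches; each of the first 2 values sets 1 library against 1 and has no spread. Basal-like pancreatic cancer subtype genes had 7 of 15 tested members higher and 0 lower, and 8 higher when adjusted over the list alone (median 0.52, camera adjusted p = 5.31e-05). That list gave adjusted p = 0.316 with an estimated correlation, and its members included TNS4, SCEL (1.34), the TEAD cofactor VGLL1 (2.07) and the keratin KRT15 (0.85).

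Mucins, part of the carcinoma surface antigens and part of the O-glycosylation genes rose. Of 5 tested mucins, 4 rose, also 4 when adjusted over the list alone, with a median of 2.30 (camera adjusted p = 0.000362, and adjusted p = 0.316 with an estimated correlation). MUC4, a membrane mucin, rose by 2.42. Of 24 carcinoma surface antigens, 9 rose and 1 fell, and 11 rose and 2 fell when adjusted over the list alone (median 0.18, camera adjusted p = 0.00105, and adjusted p = 0.316 with an estimated correlation). Of the 12 fits that left out 1 library, 7 called none of these antigens lower. Risers were the adhesion molecules CEACAM1 (1.72) and L1CAM (0.86), and TSPAN1. Of 24 genes of mucin-type O-glycosylation, 7 rose, and 10 when adjusted over the list alone (median 0.09, camera adjusted p = 0.0168, and adjusted p = 0.316 with an estimated correlation). They included GALNT5 and GALNT6 (0.81), which start the glycan chains, and the fucosyltransferases FUT3 (2.09) and FUT2 (0.94). The median of this list was -0.0089 after correction for transcript length and GC content.

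Part of the antigen presentation and interferon genes were higher. Of 7 tested genes of MHC class II presentation, 5 rose, also 5 when adjusted over the list alone, with a median of 1.59 (camera adjusted p = 0.00882, and adjusted p = 0.384 with an estimated correlation). HLA-DRA (1.84) and HLA-DPA1 (1.59), chains of the class II molecules, were among them. With a filter at 1 CPM, which left out the members with the fewest counts, the list's median was 0.39, and CD74, its invariant chain, hardly changed (0.12). Leaving out 1 library gave 2 to 5 called members of MHC class II presentation. Of 26 interferon-stimulated genes, 8 rose and 1 fell, and 17 rose and 1 fell when adjusted over the list alone (median 0.34, camera adjusted p = 2.1e-05, and adjusted p = 0.432 with an estimated correlation). IFIT2 (1.29) and OASL (1.62), antiviral effectors, rose, and BST2, an antiviral membrane protein, fell (-0.28). Leaving out 1 library gave 2 to 11 higher interferon-stimulated genes, and 4 of these 12 fits called none of them lower. MHC class I presentation had 1 of 17 tested genes higher, NLRC5 (0.55), the activator of class I genes, also 1 when adjusted over the list alone (median 0.15, camera adjusted p = 0.0274, and adjusted p = 0.487 with an estimated correlation). This last list did not pass with batch as a term (camera adjusted p = 0.119, with the median hardly moved at 0.14). It did not pass without A1 IgG-positive replicate 3 (0.0763, median 0.13), without A14 IgG-positive replicate 3 (0.165, median 0.07) or without both A1 replicate 1 libraries (0.0567, median 0.10).

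A small part of the genes of DNA replication was called lower in IgG-positive cells. Of 23 G1/S and replication genes, 3 fell, and 5 when adjusted over the list alone (median -0.12, camera adjusted p = 0.000982, and adjusted p = 0.375 with an estimated correlation). UHRF1, which maintains DNA methylation at replication, fell by 0.40 on the log2 scale. Of the 12 fits that left out 1 library, 12 called UHRF1, 10 E2F1 and 2 FEN1. Of 35 replication-dependent histones, 3 fell, and 1 when adjusted over the list alone (median -0.33, camera adjusted p = 4.72e-08, and adjusted p = 0.482 with an estimated correlation). After correction for transcript length and GC content the median of the histones was -0.104 and camera's adjusted p was 0.0974. Of the 3 called histones, HIST1H4E was called in 3 and HIST1H2BE in 2 of the 12 fits that left out 1 library, and HIST1H2BM in 10. HIST1H2BM, a histone H2B gene, fell by 0.48 on the log2 scale, and its edgeR adjusted p was 0.0647 without A1 IgG-negative replicate 2 and 0.0625 without A14 IgG-negative replicate 1. Of 77 cytosolic ribosomal proteins, 3 fell, also 3 when adjusted over the list alone, among them RPL28 (-0.55). The list's median was -0.06 (camera adjusted p = 0.00546, and adjusted p = 0.747 with an estimated correlation). Leaving out 1 library gave 1 to 3 lower members. The ribosomal list's adjusted p was 0.373 without A1 IgG-positive replicate 1, 0.209 without A14 IgG-positive replicate 2, and 0.32 with the median turned to 0.054 without both; it was 0.0778 without both A1 replicate 1 libraries. Of 19 autoantigens of pancreatic cancer sera, 2 fell, the glycolytic enzymes TPI1 and ENO1, and 3 when adjusted over the list alone (median -0.11, camera adjusted p = 0.0238, and adjusted p = 0.501 with an estimated correlation). The autoantigen list did not pass without A1 IgG-positive replicate 1 (camera adjusted p = 0.0665), without A14 IgG-positive replicate 2 (0.0724), with batch as a term (0.155) or with the length and GC correction (0.0974), and stood at 0.05 without A14 IgG-negative replicate 1. Its median was -0.10 with batch as a term and -0.13 with the correction. Camera compares the list with all other genes and the median alone does not. These medians therefore do not settle whether batch or length and GC content was the source. TPI1 and ENO1 were each called in 2 of the 12 fits that left out 1 library.

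**Figure D2:**
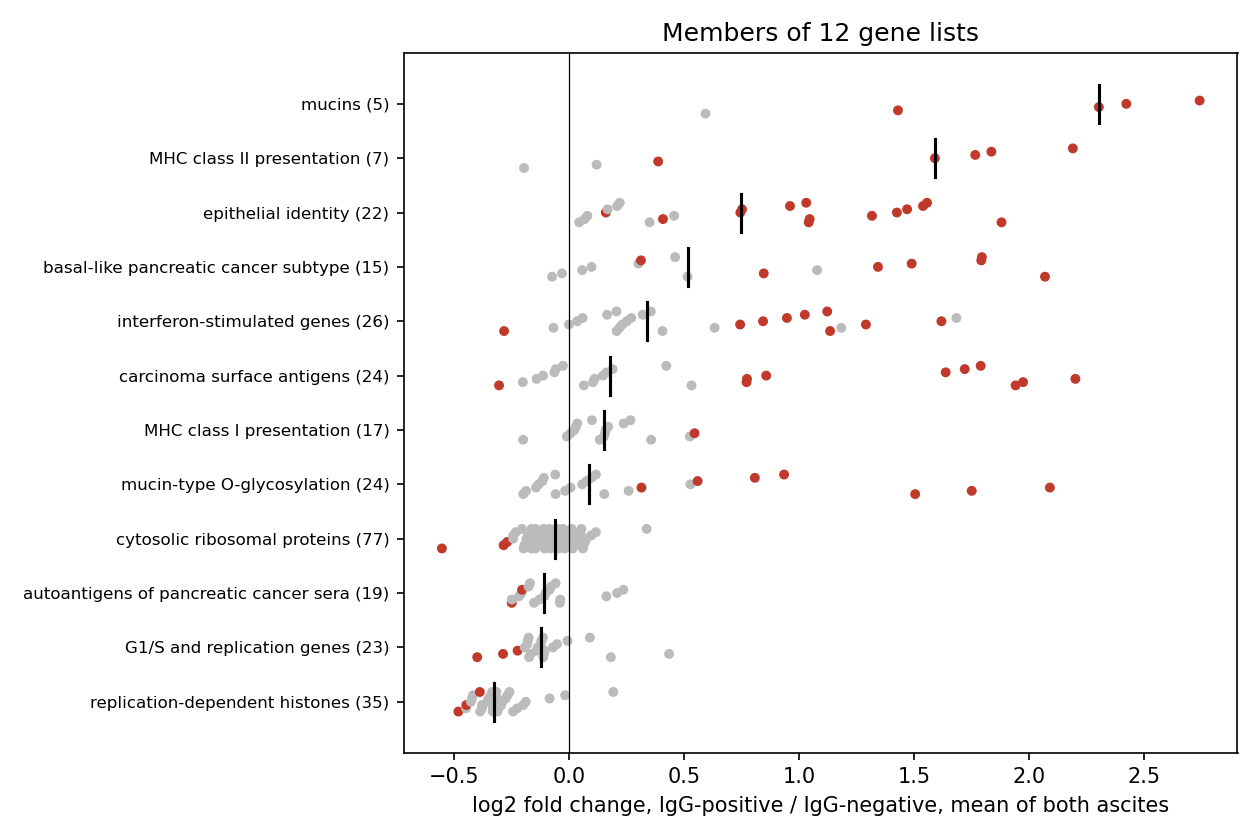
Log2 fold changes, IgG-positive against IgG-negative cells over both ascites, of the tested members of the 12 gene lists that passed camera with the preset correlation. Each point is a gene, red where its edgeR adjusted p passed, the black bar is the list's median and the number of tested members is in parentheses; the median was 2.30 for the mucins and -0.33 for the replication-dependent histones.

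Small non-coding RNAs, a class taken from the symbols after the values were seen, had 1 of 151 tested features higher and 56 lower, with a median log2 fold change of -0.75. RNY3 and RNY1 belong to this class. With the length and GC correction RNY3 kept its call (log2 fold change -1.02, edgeR adjusted p = 0.00153) and RNY1 did not (-0.04, 0.845). The trend was fitted on all tested genes of known length, small RNAs included. It can therefore take up part of the class's own shift, and the lost call does not show that length was the cause. Transcript length went with the change across 12892 genes, which are not independent replicates (Spearman rho 0.315), as did GC content (rho -0.194). Within libraries, A1 IgG-positive replicate 1 (rho 0.357) and A14 IgG-positive replicate 2 (rho 0.477) had the strongest positive trends with length. On the axes of a principal component analysis these 2 libraries had the highest values of the first component (47.8 and 30.4), which held 34.9% of the variance.

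In all, edgeR called 1501 of 14337 tested genes between the fractions over both ascites, 878 higher and 623 lower, and 328 of them changed at least 2-fold. Leaving out A1 IgG-negative replicate 2 gave 594, A1 IgG-negative replicate 3 gave 687, A1 IgG-positive replicate 2 gave 791, A14 IgG-negative replicate 1 gave 666 and A14 IgG-negative replicate 2 gave 943. With the replicate number as a block the count was 1151. With the length and GC correction 2538 genes were called, of which 37.1% were higher, against 58.5% without it. With batch as a term edgeR called 0 genes (1090 at an unadjusted p under 0.05; DESeq2 was run without batch and called 2337), and within the 4 libraries of batch 2 it called 1, the ribosomal RNA feature RNA5-8S5, named after its value was seen; batches 1 and 3 each held a single fraction.

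With ascites A1 alone, the same membrane mucins and epithelial regulators rose. MUC16 rose 8.01-fold (log2 fold change 3.00 ± 0.66 SE, n = 3 per group; edgeR adjusted p = 0.0390) and MUC1 rose 6.08-fold (2.60 ± 0.52; edgeR adjusted p = 0.0331). PVRL4, the adhesion molecule nectin-4, rose 5.57-fold (2.48 ± 0.46; edgeR adjusted p = 0.0289), and GRHL2 rose 4.40-fold (2.14 ± 0.29; edgeR adjusted p = 0.0178). RNY3 had a log2 fold change of -2.30 ± 0.41 (edgeR adjusted p = 0.0267), and HNRNPA0 one of -0.80 ± 0.10 (edgeR adjusted p = 0.0103). Of the 12 fits that left out 1 library, the call was kept in 4 for MUC16, 7 for MUC1, 7 for PVRL4, 9 for GRHL2, 8 for RNY3 and 9 for HNRNPA0. Fits without an A14 library kept all the A1 libraries, so they test these calls less. MUC16 lost its call whichever A1 library was left out (edgeR adjusted p 0.0525 to 0.186). All lost calls of PVRL4, GRHL2, RNY3 and HNRNPA0 fell in fits without an A1 library. Without A1 IgG-positive replicate 1 the log2 fold change was 2.36 for MUC16 (edgeR adjusted p = 0.0657) and 1.87 for MUC1. Without A1 IgG-negative replicate 1 it was 3.62 for MUC16 (0.063), and with the replicate block the adjusted p of MUC16 was 0.0571. EHF rose 4.60-fold. On the log2 scale SERPINB5 (2.15), TNS4 (2.10), ADGRF1 (2.07), the protocadherin PCDH1 (1.93) and the sodium leak channel NALCN (1.93) also rose. ND6 (-1.17), RNY1 (-1.11), RERG (-0.99), CTNNA2 (-0.91), KRT10 (-0.83), the iron exporter SLC40A1 (-0.80), the heparan sulfate enzyme HS3ST1 (-0.78) and DPM3 (-0.77), a subunit of dolichol-phosphate mannose synthase, fell. With the replicate block RERG (edgeR adjusted p = 0.0588) and KRT10 (0.0624) did not pass, and with the length and GC correction RNY1 did not (0.819).

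Of the 32 lists tested, 11 passed camera with A1, 0 passed with an estimated correlation and 8 passed with fry. Epithelial identity had 7 of 22 members higher, and 15 when adjusted over the list alone (median 0.74, camera adjusted p = 1.53e-09, and adjusted p = 0.366 with an estimated correlation). Of 5 mucins, 3 rose, and 4 when adjusted over the list alone (median 2.56, camera adjusted p = 0.000218, and adjusted p = 0.366 with an estimated correlation). Interferon-stimulated genes had 0 of 26 members called by edgeR over all genes and 9 higher and 1 lower when adjusted over the list alone (median 0.41, camera adjusted p = 3.71e-05, and adjusted p = 0.51 with an estimated correlation).

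For A1, edgeR called 400 genes, 218 higher and 182 lower, and 156 of them changed at least 2-fold; DESeq2 called 1135. With 1 replicate-number block shared by both ascites 220 genes were called. A block within the 6 A1 libraries alone, chosen after seeing the data, matches the pairing in this ascites and gave 1032. With batch as a term the count was 0 (1041 at an unadjusted p under 0.05). Leaving out 1 library gave 0 genes without A1 IgG-negative replicate 2, 2 without A1 IgG-negative replicate 3, 3 without A1 IgG-positive replicate 2, 61 without A1 IgG-positive replicate 3 and 79 without A1 IgG-negative replicate 1. The column of A1 IgG-negative replicate 2 carries a tag in its name that the labels do not explain. The A1 count was 157 without A14 IgG-negative replicate 2, 203 without A14 IgG-negative replicate 3, 196 without A14 IgG-positive replicate 1 and 928 without A14 IgG-positive replicate 2. The genes in the smallest counts, named after their values were seen, were SH3TC2 and RNU5D-1 in both and ANK3 where 3 were called.

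With ascites A14 alone edgeR called no gene, while DESeq2 called 177, and the genes with the smallest edgeR p included GRHL2 and HNRNPA0. SH3TC2, an adaptor protein of endosomes (chromosome 5, 148982150 to 149063062), stood at 50.7 ± 9.35 CPM in IgG-negative and 99.0 ± 9.75 in IgG-positive cells (SD, n = 3 per group), a log2 fold change of 0.97 ± 0.13 SE (edgeR adjusted p = 0.0925). GRHL2 had a log2 fold change of 1.63 ± 0.29 (edgeR adjusted p = 0.160), and TMEM265 (2.03-fold), KIAA1211L (2.46-fold) and C1orf116 (2.36-fold) each had an edgeR adjusted p of 0.132. On the lower side were HNRNPA0 (-0.64 ± 0.10; edgeR adjusted p = 0.132), the tubulin TUBB2B (-0.47), the myosin chaperone UNC45A (-0.36), AP2M1, a subunit of the clathrin adaptor AP2 (-0.41), and KRT10 (-0.81).

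The lists did pass with A14: 13 of 32 by camera, and 0 with an estimated correlation or with fry. Epithelial identity had 22 of 22 members above 0, 0 called by edgeR over all genes and 13 when adjusted over the list alone (median 0.75, camera adjusted p = 5.25e-11, and adjusted p = 0.201 with an estimated correlation). Mucins had 4 of 5 higher when adjusted over the list alone (median 2.00, camera adjusted p = 0.000198, and adjusted p = 0.201 with an estimated correlation). Carcinoma surface antigens had 7 of 24 higher when adjusted over the list alone (median 0.18, camera adjusted p = 0.000176, and adjusted p = 0.201 with an estimated correlation). Interferon-stimulated genes had a median of 0.28 (camera adjusted p = 6.26e-05, and adjusted p = 0.492 with an estimated correlation), and camera's adjusted p for them was 0.186 without A14 IgG-positive replicate 3. Without that library 8 lists passed.

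For A14, edgeR called 0 of 14337 genes, with 1460 at an unadjusted p under 0.05, and DESeq2 called 177. Without A14 IgG-positive replicate 2 edgeR called 64 genes, without A1 IgG-negative replicate 1 it called 1, RNA5-8S5. With batch as a term it called 0 (479 at an unadjusted p under 0.05).

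The changes with the 2 ascites were compared gene by gene. Of the 400 genes called with A1, 400 had the same direction with A14 and 350 also had an unadjusted p under 0.05 there. The contrasts set different libraries against each other, but both came from 1 fit with 1 spread estimate per gene. The A14 p values of genes chosen on A1 are therefore not independent of that choice, and the 350 is not a separate replication. Of all tested genes 83.5% had the same direction, and both contrasts had the same layout of batches. The rising A1 genes had a median log2 fold change of 1.11 with A1 and 0.77 with A14, and the falling ones -0.47 and -0.31. Because the genes were chosen on A1, the smaller A14 medians are not a test of a difference. Across all tested genes, which are not independent replicates, Pearson's r was 0.717 and Spearman's rho 0.784.

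**Figure D3:**
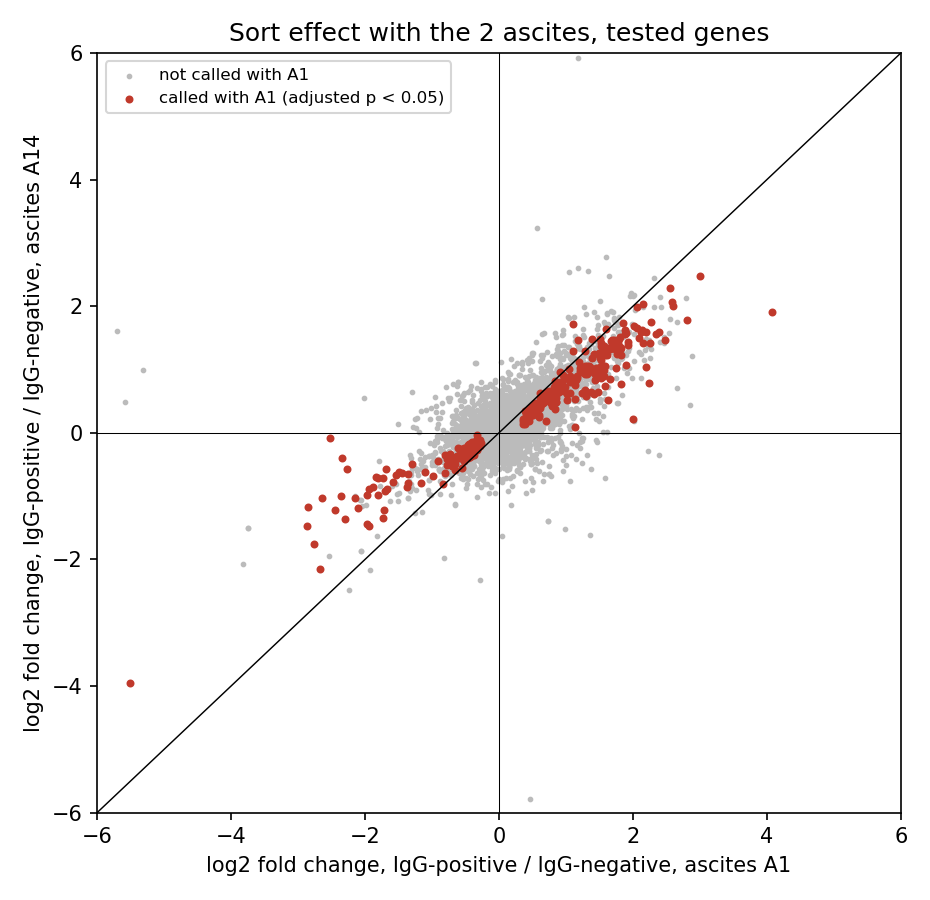
Log2 fold change, IgG-positive against IgG-negative cells, with ascites A1 on the x axis and ascites A14 on the y axis, for the 14337 tested genes less 11 beyond the axis limit of 6. Each point is a gene, red where edgeR called it with A1, and the line is the diagonal; the 400 red genes have the same sign in both ascites.

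The test of the difference itself asked whether the sort effect depended on the ascites. Among the genes with the smallest p, SOCS1, a suppressor of cytokine signalling, had a difference, A14 less A1, of 0.71 ± 0.22 on the log2 scale, the lipid enzyme TECR one of 0.24 ± 0.09, and TIGD5 one of 0.46 ± 0.17. TGFBR2, a receptor for TGF-beta, had -0.51 ± 0.16, WHAMMP1 -0.37 ± 0.17 and HARBI1 -0.44 ± 0.20. All 6 failed the correction with an edgeR adjusted p of 1.00. EdgeR called 0 genes for the difference, with 82 at an unadjusted p under 0.05, and DESeq2 called 0. The 82 are fewer than the share of 0.05 of tested genes that evenly spread p values would give. Recovery was not simulated for this comparison, so the 0 does not show that the sort effect was the same.

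Ascites A14 was also compared with A1 over both sort fractions, and most of the list differences given here lay in 1 pair of libraries, A1 replicate 1. Lower with A14, by camera, were the immediate-early genes, the first responders to stimuli, with 1 of 21 members above 0 (median -0.29, adjusted p = 1.45e-06, and adjusted p = 0.823 with an estimated correlation). The mitochondrially encoded genes, which serve respiration, had 0 of 13 members above 0 (median -0.42, camera adjusted p = 1.34e-06, and adjusted p = 0.823 with an estimated correlation). Genes of hypoxia and glycolysis were lower (median -0.23, camera adjusted p = 0.00039, and adjusted p = 0.823 with an estimated correlation), and camera's adjusted p was 0.222 without A1 IgG-negative replicate 1 and 0.254 without A1 IgG-positive replicate 1. G2/M genes were higher with A14 (median 0.11, camera adjusted p = 3.98e-05, and adjusted p = 0.823 with an estimated correlation), and camera's adjusted p was 0.0583 without A1 IgG-positive replicate 1. In all 8 lists passed camera at the preset correlation and 0 with an estimated one or with fry; 3 passed without A1 IgG-negative replicate 1, 2 without A1 IgG-positive replicate 1 and 5 without A14 IgG-negative replicate 1. Without the 2 libraries with the strongest length trends the adjusted p of the immediate-early genes was 0.131. Also among the 8 were mucins (median -0.65), the unfolded protein response (-0.06), replication-dependent histones (0.13) and cytosolic ribosomal proteins (0.04). Without both A1 replicate 1 libraries, a fit chosen after seeing the data, 3 lists passed, 2 of them among the 8. There the medians were -0.22 for mucins, -0.02 for the unfolded protein response, -0.01 for histones and -0.04 for ribosomal proteins. The median of the immediate-early genes was then -0.04 (camera adjusted p = 0.319), that of the G2/M genes 0.03 (0.667), and that of hypoxia and glycolysis turned to 0.06 (0.238). The mitochondrially encoded genes still passed (0.0312) with a median of -0.09. The differences of the immediate-early, mitochondrially encoded, hypoxia and G2/M genes rest mostly on 1 pair of libraries and are not taken as an effect of the ascites.

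Of single genes, edgeR called 0 between the ascites, with 220 at an unadjusted p under 0.05, and DESeq2 called 0. The 220 are also fewer than a share of 0.05 of tested genes, and recovery was not simulated here, so the 0 does not show that the ascites were alike. The smallest p values belonged to SLC40A1 (log2 difference 0.36 ± 0.09 SE), the calcium channel subunit CACNA2D3 (0.59 ± 0.17) and FAM64A (0.30 ± 0.09) on the higher side with A14. The kinase BRSK2 (-0.49 ± 0.13), the mitochondrial ATP synthase subunit ATP8 (-0.45 ± 0.12) and MYADM (-0.30 ± 0.10) were on the lower side. Each had an edgeR adjusted p of 0.988.

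Most leukocyte markers were near the floor. Of 33 leukocyte markers in the table, 23 had at most 3 counts in every library. PTPRC, the leukocyte antigen CD45, had 1 count in all 12 libraries together, and TYROBP had 0, which allows up to 0.0144 CPM in the pooled IgG-negative and 0.0224 in the pooled IgG-positive libraries, for counting error only. Of 5 tested mesothelial markers, 2 were called higher, the complement component C3 (1.69), which is also on the complement list, and BNC1 (0.91), and the list did not pass over both ascites (camera adjusted p = 0.0627). Leaving out 1 library gave 0 to 2 called members, and with batch as a term the list's median was 0.09 against 0.56. With A14 the mesothelial list passed (median 0.69, camera adjusted p = 0.03, and adjusted p = 0.201 with an estimated correlation). It did not pass there with batch as a term (0.168), without A14 IgG-negative replicate 2 (0.107), without A14 IgG-positive replicate 3 (0.187) or without the 2 libraries with the strongest length trends (0.0773). Of the Fc receptors and IgG-binding proteins, 3 could be tested and 0 were called by edgeR (camera adjusted p = 0.579).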

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

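The tests here were planned, except the length and GC correction and the fits without 2 libraries, which were chosen after the data were seen. The sort effect on 2 gene lists differed between the ascites by camera on the interaction at the preset correlation. Replication-dependent histones differed with an adjusted p of 0.0281: their median log2 fold change was -0.40 with A1 and -0.25 with A14, the median of the differences was 0.16, and 34 of 35 members were above 0. Epithelial identity differed with the same adjusted p of 0.0281: its medians were 0.74 and 0.75, the median of the differences was -0.11, and 9 of 22 members were above 0. Both gave adjusted p = 0.982 with an estimated correlation and 1 with fry.

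Chance could not be excluded for these differences, since 97 of 100 splits gave at least as many passing lists (real 2, highest other 17). The number of passing lists was 4 without A1 IgG-negative replicate 1, 6 without A1 IgG-positive replicate 1, 8 without A14 IgG-negative replicate 1 and 7 without A14 IgG-positive replicate 3, and 1 without A1 IgG-negative replicate 3, A1 IgG-positive replicate 2, A14 IgG-negative replicate 2, A14 IgG-negative replicate 3 or A14 IgG-positive replicate 1. The difference for histones ended without A1 IgG-negative replicate 2 (adjusted p = 0.732), A1 IgG-negative replicate 3 (0.0689), A14 IgG-negative replicate 2 (0.63), A14 IgG-negative replicate 3 (0.113), A14 IgG-positive replicate 1 (0.582) or A14 IgG-positive replicate 3 (0.511). It also ended without A1 IgG-positive replicate 1 (0.877, where camera's direction turned while the median stayed above 0 at 0.03) and without both A1 replicate 1 libraries (0.199). With the length and GC correction it ended as well (0.833), and there the median turned to -0.03. That for epithelial identity ended without A1 IgG-negative replicate 1 (0.228), A1 IgG-positive replicate 2 (0.0773), A1 IgG-positive replicate 3 (0.13), A14 IgG-negative replicate 2 (0.303, median 0.01), A14 IgG-negative replicate 3 (0.0607) or both A1 replicate 1 libraries (0.404). Camera's direction and the median (0.05) both turned without A14 IgG-positive replicate 2 (0.975). Without the 2 libraries with the strongest length trends camera's direction turned (0.908) while the median stayed below 0 at -0.07. With batch as a term the adjusted p was 0.0606 for both lists, and with the replicate block it was 0.0596 for the histones.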

How the results depend on the processing

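The length and GC correction, the blocked fits of 6 libraries, the fit without the 2 libraries with the strongest length trends and that without both A1 replicate 1 libraries were chosen after seeing the data. With A1, 400 genes became 220 with the replicate block, 0 with batch as a term, 156 with a 2-fold minimum, 1032 with the 6 A1 libraries and the block, 746 with the correction, 1293 without the 2 libraries, 46 without the A1 replicate 1 pair and 1135 with DESeq2; leaving out 1 library gave 0 to 928. With A14, 0 became 1 without the filter (SH3TC2), 1 with its 6 libraries alone, with these and the block, or without the A1 pair (RNA5-8S5 in all 3), 122 without the 2 libraries and 177 with DESeq2; leaving out 1 library gave 0 to 64. For the mean, 1501 became 0 with batch as a term, 328 with a 2-fold minimum, 1 in batch 2, 2538 with the correction and 2337 with DESeq2; leaving out 1 library gave 594 to 1723. The difference between ascites and A14 against A1 stayed at 0 in every fit run. With an estimated correlation 0 lists passed in each comparison. With fry, which does not compare a list with other genes, 8 passed for A1, 11 for the mean and 0 for A14, the difference and A14 against A1. Lists for the difference numbered 1 with the block, 0 with batch, 1 with the correction and 0 without the A1 pair, and those for A14 against A1 numbered 4 without the 2 libraries and 3 without the A1 pair. Leaving out 1 library gave 11 to 13 lists for A1, 8 to 14 for A14, 10 to 14 for the mean, 1 to 8 for the difference and 2 to 9 for A14 against A1. Apart from the 2-fold minimum, the 6 or 4 libraries and the left-out libraries, which change the bar or the sample, the cause was not tested. Of 92 results for named genes 74 were calls. All 74 were lost with batch as a term, 7 with the block, 6 without the 2 libraries and 3 with the correction, and none changed direction in these fits. The batch term itself was called for 0 genes (131 at an unadjusted p under 0.05, fewer than that share of tested genes), which does not show that batch had no effect. In A14 same-numbered libraries correlated at 0.199, -0.005 and 0.214, and 4 of 6 libraries correlated best with the library of their own number. No pairing was taken there, though these values do not exclude one. At these depths a log2 change of 0.5 was rarely recovered in a single ascites (0% and 2% of simulated genes).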

Other observations

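The tests of batch and of leukocytes for the epithelial genes and that of short mRNAs for the small RNAs were chosen after the results were seen, as was the class of small RNAs itself. Some genes outside the passing lists also changed over both ascites. Of 19 integrins and laminin-332 genes, 5 rose and 1 fell, also 5 and 1 when adjusted over the list alone, among them LAMB3 (0.96), a chain of laminin-332, and the tetraspanin CD9 (0.95), while CD151 fell (-0.28); the list did not pass (camera adjusted p = 0.131). Of 6 tested classical pancreatic cancer subtype genes, 3 rose, PRR15L (1.85), CTSE (1.45) and LYZ (1.29), camera adjusted p = 0.159. With A14 this list passed (camera adjusted p = 0.035, and adjusted p = 0.201 with an estimated correlation). It did not pass there without A1 IgG-positive replicate 1 (0.0748), A14 IgG-negative replicate 1 (0.0519), A14 IgG-negative replicate 3 (0.0721), A14 IgG-positive replicate 1 (0.212), both A1 replicate 1 libraries (0.0814) or the 2 libraries with the strongest length trends (0.0547). The list's A14 median was 0.695 in the main fit and 0.642 to 0.741 in these fits.

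FN1 (0.50) and SPARC (0.94), matrix proteins, rose among 12 mesenchymal transition genes (camera adjusted p = 0.159), beside the epithelial ones. HSPA5 (0.69), the chaperone of the endoplasmic reticulum, and EDEM1 (0.36) rose among 18 genes of the unfolded protein response, whose median (-0.02) and mean (0.07) differ in sign (camera adjusted p = 0.579). TNFAIP3 (0.67), an inhibitor of NF-kB signalling, was the 1 called member of 16 inflammatory genes (camera adjusted p = 0.976). MAGEA2B (1.45) was called among the 2 tested cancer-testis antigens. Leaving out 1 library gave 0 to 1 higher cancer-testis antigens, 1 to 3 mesenchymal transition genes and 1 to 2 unfolded protein response genes. The mitochondrially encoded genes had 3 of 13 lower, with a median of 0.08 and a mean of -0.02 (camera adjusted p = 0.209).

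Epithelial identity genes were higher in IgG-positive cells by 0.737 ± 0.132 (SE) in mean log2 CPM. After correction for transcript length and GC content the difference was 0.702 ± 0.144, which argues against those trends as the whole cause. With batch as a term it was 0.675 ± 0.263, more than 2 standard errors above 0, although no single gene passed that fit. Only batch 2 holds both fractions, so this estimate rests on its 4 libraries and is not separate from the values within batch 2. Carry-over of leukocytes from the ascites would bring their abundant transcripts, but 23 of 33 leukocyte markers had at most 3 counts in every library. Immunoglobulin constant genes were not among the symbols. These markers bear on leukocytes only, so they do not test other sources of the epithelial rise. A candidate explanation that stays open, as a hypothesis found on these data and not itself tested, is a more epithelial state of the cells binding ascitic IgG. The sort cannot tell that from an effect of the staining itself, and the mesenchymal transition genes FN1 and SPARC also rose.

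Small non-coding RNAs were lower in IgG-positive cells by a difference of -0.849 ± 0.222 (SE) over 151 features. After thinning all libraries to the smallest total it was -0.805 ± 0.206. Thinning keeps each feature's expected share of its library, so it argues only against an effect of low counts on the log2 scale. It cannot test what made the IgG-positive libraries smaller. A length-dependent loss of short RNA could account for the lower small RNAs. The 317 mRNAs under 1000 bases differed by -0.0179 ± 0.082, too close to 0 to decide, and they do not reach the size of the small RNAs. With batch as a term the difference was -0.6 ± 0.361, within 2 standard errors of 0, so batch and sort cannot be told apart for it. Within batch 2, with 1 library against 1 and no spread, it was -0.563 with A1 and -0.638 with A14. The estimate with batch as a term rests on these same libraries. No biological explanation was tested.

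EdgeR called genes with A1 and none with A14, where DESeq2 called 177. The spread of A14 IgG-positive replicate 2 could account for that. Without it edgeR called 64 genes with A14 and 928 with A1 in the same fit. That fit leaves A14 with fewer libraries than A1, and the A1 count itself fell to as few as 0 without 1 A1 library. It therefore cannot decide whether that library accounts for the gap. The difference between the ascites itself was tested and called 0 genes, so the counts do not show that the ascites differ. Whether the IgG of the 2 fluids differs in what it binds stays open.

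Other splits of the libraries gave the following. For the mean, libraries were exchanged between the fractions within each ascites. Of 100 splits 1, the real one, called as many genes (1501, highest other 158), so chance was excluded for that count if the libraries are independent. The labels do not say whether they are. The real split also nearly followed the batch, so its count cannot tell the sort from the batch. As many passing lists came from 17 of 100 splits (12, highest other 17), so chance was not excluded for the number of lists. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: for A1 the real split, 1 of the 10, called 400 genes (highest other 0, also among the splits that part all 3 same-numbered pairs; the others keep 2 pairs together), and 2 splits gave as many lists (11, highest other 11). For A14 all 10 splits called as many genes (0, highest other 0), and 1 gave as many lists (13, highest other 11). For the difference, 100 of 100 splits called as many genes (0, highest other 1562), and for A14 against A1 100 of 100 did (0, highest other 996) and 36 of 100 gave as many lists (8, highest other 14), so chance was not excluded; counts that high point to a structure of the samples, whose nature was not tested.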
